A study of Homo sapiens with 17 samples.

How the data were processed

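Chromatin of HCC1954 cells, a HER2-positive human breast cancer cell line, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) after transfection with antisense oligonucleotides, per the labels' protocols, with cells fixed 72 hours later. The labels name 2 arms, NC1235 and Si1235, and the series title names the long non-coding RNA LINC01235. The labels do not spell out what NC and Si stand for, so the arms keep those names here. The 17 samples comprised 2 libraries per arm for each of H2A.Z (written H2AZ here, as in the labels), H3K27ac and H3K36me3, 1 library per arm for H3K9ac, 1 input per arm, and 1 library of chromatin isolation by RNA purification (ChIRP), a method that recovers the DNA bound near a chosen RNA with antisense probes. The ChIRP title carries the name NC1235, and the RNA captured by the probes is not given in the sources used here. The labels do not say that replicates were separate cultures, so limma and relabeling p-values below measure the spread between these libraries, which may be technical. Camera p-values set the members of a gene list against the other tested genes. At the preset correlation of 0.01 they treat the members as nearly independent, so they do not measure the spread between libraries. ChIRP placement and Fisher p-values concern positions and regions only.

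Reads were aligned with Bowtie2 2.2.9 to hg38 and peaks were called with MACS2, per the submitters' processing notes, which also list HTSeq 2.0.3 and DESeq2 1.22.2 without saying what they were applied to. No MACS2 version or setting is given in the sources used here, nor is the control used in peak calling. The files analysed were 15 peak lists, 1 per library and none pooled. The 2 input samples have no peak list used here. In each list the authors' peak caller gave a fold enrichment, a linear ratio of the peak summit over local background, and −log10 values of the p-value and of the q-value. The lowest deposited −log10 q-value in any list was 2.00029, so the lists hold only peaks past a q-value threshold. The deposited peak names in 2 lists, both of H3K9ac, carry the name of another histone residue, and the labels were followed. The fold enrichment is the authors' own value and was used only to describe or rank peaks within a list. No read counts were used, so depth was read indirectly. The fold enrichment and −log10 p of weak peaks were solved for the whole-number read pileup and the background that give both, within a tolerance of 0.002, on 1500 peaks per library. Whole pileups came out for all solved peaks in 13 libraries and for 0.4% and 1.2% of them in the NC1235 H3K27ac replicates 1 and 2, whose pileups were therefore taken as scaled.

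Peaks on chromosomes 1 to 22 and X were kept. Gene positions came from the RefSeq table of GRCh38.p14, the same assembly as hg38, for protein-coding and lncRNA genes with a unique symbol. No peak and no gene of the table lay beyond a chromosome end, with 0 of each. The planned promoter window was the transcription start site ± 1.0 kb. The table gives no strand, so the window was placed instead at the end of the gene with more peak cover of the promoter marks other than the one tested. Of 25 checked genes of known strand, this rule gave an end to 23 for H2AZ, 24 for H3K27ac and 24 for H3K9ac, each the known start. It placed the NFIB window away from the promoter, so windows of other genes may lie there too. The windows of H2AZ and H3K27ac lay at the same end in 98.0% of 19201 genes. The end is the outermost one of the annotated gene, so a window can miss the start of a shorter transcript. Genes with equal cover of the other promoter marks at both ends, which includes no cover at either, had no window. They numbered 18712 for H2AZ and 17676 for H3K27ac. The H3K36me3 window was the gene body of protein-coding genes of at least 2.0 kb.

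For each library the percent of each window covered by peaks was computed. Genes with a mean cover of at least 5% over the 4 libraries of a mark were tested with limma, with an intensity trend and without a replicate term, on differences in percentage points (Si1235 minus NC1235). P-values were adjusted by the Benjamini-Hochberg method over the genes of a mark, with a threshold of 0.05. The 21 gene lists, with 493 genes in all, covered DNA replication, the cell cycle, chromatin machinery, HER2 and its amplicon, the interferon and nucleic acid response, p53, apoptosis, ribosomal proteins, histone genes and markers of luminal, basal, mesenchymal, immune and endothelial cells. Lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 and again with the correlation estimated from the data. Union regions were formed from the 4 lists of a mark by merging peaks that overlapped or touched. A region was called lost when both NC1235 libraries and neither Si1235 library had a peak in it (overlap of at least 1 bp), gained in the reverse case, and kept when all 4 had one. These counts were set against the other 2 ways to pair the 4 libraries. Peak number and covered length were compared with an exact two-sided permutation test over the 6 relabelings of 4 libraries, whose smallest p is 0.333. ChIRP peaks were placed 1000 times at random within chromosomes, and lost and gained regions were compared with kept ones by Fisher's exact test. Binomial intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

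Genes were named by a rule fixed before the data were examined, as were the groups, tests, gene lists and most alternatives. For each mark the rule takes up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold whose arms did not overlap. Where fewer passed, it fills up to 5 per direction with non-passing genes, given as values only. It adds the 2 members with the largest change of each list, LINC01235, NFIB and ERBB2. For regions it takes the 3 lost and the 3 gained with the highest fold enrichment in the weaker of their 2 libraries, for H3K9ac the 8 largest differences each way, and for ChIRP the 5 peaks of highest fold enrichment. EZH2 and a list of sterol synthesis genes were chosen after their values were seen, as was the description of H3K27ac regions at called windows. Regions are named by the gene they lie in or the nearest gene, and also by the nearest coding gene where given.

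The steps were tested on simulated data. Covered bases matched a base-by-base count in 1000 windows and a simulated background was recovered in 500 peaks, with 0 errors in each. Of 50 genes given a change of 60 points at each gene's own spread, limma called 0 for H2AZ (17364 genes tested), 0 for H3K27ac (16026) and 40 for H3K36me3 (8349). Simulated cover was cut at the ends of its range, so the median estimate of that change was 49.0, 48.9 and 47.3 points. The spread of each gene was the one observed between these libraries. With a spread of 1 point it called 48 of 50 changes of 10 points for H3K27ac. A gene is therefore called mainly where both libraries of each arm lie close together, and a lack of calls is not a lack of change.

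Alternatives tried were peaks with −log10 q of at least 5, an equal number of top peaks per library, each library left out in turn, the replicate number as a block, other filters and scales (no filter, 20% cover, an arcsine square root, quantile normalization), windows of ± 2.5 kb or the 3′ part of the gene body (50%), merging within 500 bp, overlap of at least 50% of the region or peak, other placements of ChIRP peaks and matching on region width. Windows at both gene ends, placement of ChIRP peaks within occupied 100 kb bins, and counts of non-overlapping changes of at least 20 points were chosen after seeing the data. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.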

Results

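The data comprised 15 peak lists of HCC1954 breast cancer cells in the NC1235 and Si1235 arms, from ChIP-seq of the histone variant H2AZ and the histone marks H3K27ac, H3K9ac and H3K36me3, and from 1 ChIRP library. H2AZ and the acetyl marks lie at active promoters and enhancers, and H3K36me3 lies over the bodies of transcribed genes. Lists held 42759 to 51229 peaks for H2AZ, 44836 to 48391 for H3K27ac, 67302 to 81320 for H3K36me3, 59945 and 60035 for H3K9ac, and 128273 for ChIRP. Depth is not stated in the lists. The background level solved from weak peaks was lower in replicate 2 than in replicate 1 of each replicated mark and arm, at 0.808 against 1.20 reads per position in NC1235 H2AZ and 0.788 against 1.10 in Si1235 H3K36me3. In the NC1235 H3K27ac lists these levels, 1.643 and 1.535, rest on scaled pileups and do not give depth. Elsewhere replicate number tracked this indirect measure of depth. Values within each number are therefore given beside pooled ones.

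The series addresses LINC01235, a long non-coding RNA gene at chromosome 9: 13406380–13431329 (hg38). Peak lists carry no RNA level, so they do not check the knockdown itself. A peak of H2AZ (13427690–13428410 in NC1235 replicate 1) and of H3K27ac (13427716–13428162 there) lay inside the gene in each of the 4 libraries of either mark. The strongest H3K27ac peak in the gene had a fold enrichment of 8.11 and 11.02 in NC1235 and of 11.7 and 7.96 in Si1235. No H3K36me3 peak lay in the gene in any of the 4 libraries, and H3K9ac had 1 peak in NC1235 and 3 in Si1235. LINC01235 itself had no tested promoter window. A broad H3K27ac domain outside the gene, starting at 13483281 in NC1235 replicate 1 and at 13483276 in Si1235 replicate 2, was present in all 4 libraries. For NFIB, a transcription factor gene on the same chromosome, the window lay at the end away from the promoter and gives no promoter value. H3K36me3 over the NFIB body (14081843–14532077) covered 14.3 ± 2.505% in NC1235 and 13.5 ± 1.70% in Si1235 (SD, n = 2), with a limma adjusted p of 0.997. ERBB2, the gene of the HER2 receptor, at chromosome 17: 39688094–39728658, differed by 2.25 points for H2AZ, 3.63 for H3K27ac and 2.72 for H3K36me3. None of the 3 differences at ERBB2 passed, with limma adjusted p of 0.903, 0.602 and 0.975. Mean cover there was 91.6, 86.3 and 56.0% in NC1235 and 93.9, 89.9 and 58.7% in Si1235. The H2AZ and H3K27ac levels left little room for a rise. Both Si1235 libraries lay above both NC1235 libraries for each mark. Arms did not overlap, in either direction, at 31.9, 41.1 and 34.0% of all tested genes.

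**Figure D1:**
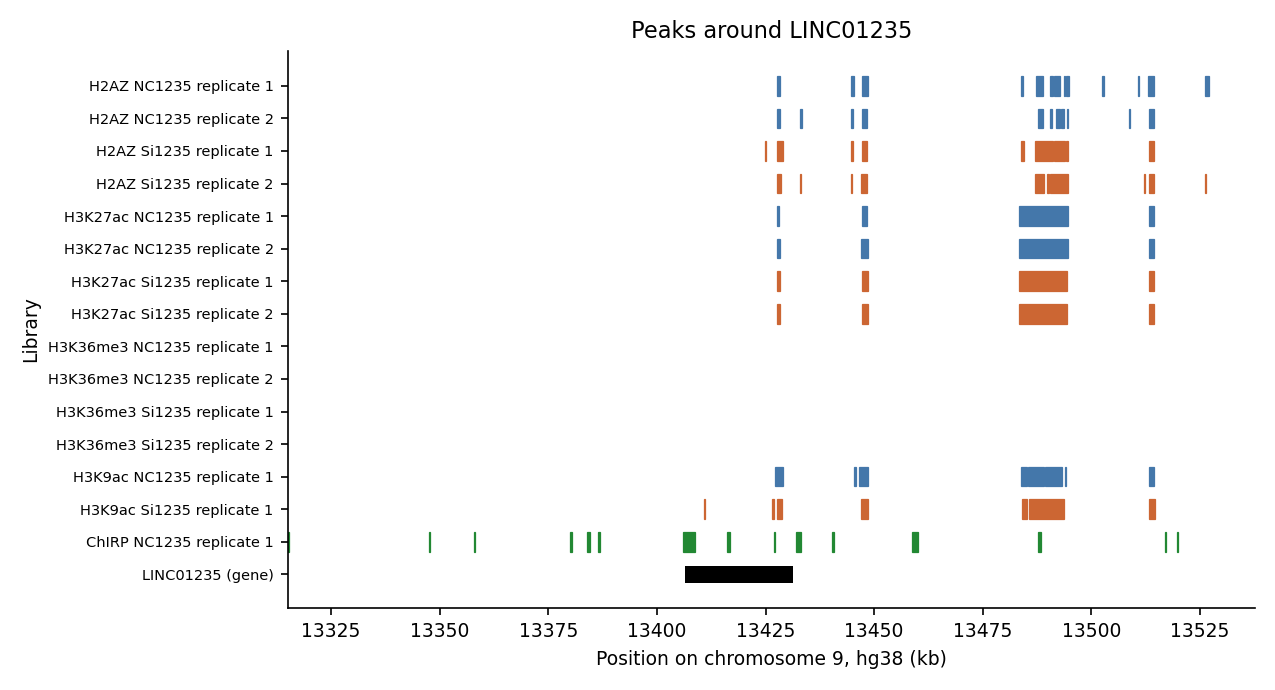
Peaks of each library (y axis) around LINC01235 on chromosome 9 (x axis, position in kb, hg38), with NC1235 in blue, Si1235 in orange and ChIRP in green; the black bar is the annotated gene. H2AZ and H3K27ac peaks inside the gene are present in all 8 libraries of these marks, and H3K36me3 has none.

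The first comparison asked whether the amount of each mark differed between the arms. H3K36me3 had more peaks in Si1235, with 78073 ± 4591.95 against 69171.5 ± 2643.87 (SD, n = 2), a log2 ratio of 0.17 that was 0.15 within replicate 1 and 0.19 within replicate 2. H3K36me3 covered about the same length, with 132.3 ± 11.7 Mb in Si1235 and 130.8 ± 18.7 Mb in NC1235, and its mean peak width was 1702 bp against 1898 bp. H2AZ had 45726.5 ± 4196.68 peaks over 40.3 ± 6.36 Mb in Si1235 and 48891.5 ± 3305.72 over 41.6 ± 5.50 Mb in NC1235. H3K27ac had 46256.5 ± 1000.56 peaks over 67.9 ± 3.16 Mb in Si1235 and 46613.5 ± 2513.76 over 69.7 ± 0.292 Mb in NC1235. The log2 ratio of peak number within replicates 1 and 2 was −0.07 and −0.12 for H2AZ and 0.02 and −0.04 for H3K27ac. The exact permutation test of peak number gave p = 0.333 for H3K36me3, the smallest that 4 libraries allow, 0.667 for H2AZ and 1 for H3K27ac, so none could pass 0.05. Leaving out NC1235 replicate 2 or Si1235 replicate 1 turned the sign for H3K27ac peak number, to 0.04 and 0.01, and for H3K36me3 covered length, to −0.13 and −0.07. Leaving out Si1235 replicate 2 did so for the covered length of H2AZ, to 0.11, and of H3K27ac, to 0.01, and NC1235 replicate 1 for H2AZ, to 0.08.

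The next comparison asked which regions held a mark in 1 arm alone. H3K27ac had 3003 regions in both NC1235 libraries and neither Si1235 library, called lost, and 2040 in the reverse pattern, called gained, among 52015 regions. The other ways to pair the 4 H3K27ac libraries gave 338 and 338 regions by replicate number, and 197 and 453 when crossed. Lost H3K27ac regions of highest fold enrichment lay in FAM157B (chromosome 9: 138221532–138221856, 21.1 and 20.6 in the NC1235 libraries), 49278 bp from LOC107986324 (chromosome 4: 159490025–159491044, 17.9 and 22.3) and in POM121C (chromosome 7: 75442438–75443031, 16.3 and 16.1). Gained ones lay 2029 bp from MRPL48 (chromosome 11: 73783731–73785844, 15.7 and 13.1 in the Si1235 libraries), in LOC107984778 (chromosome 15: 91410965–91412681, 12.4 and 16.2) and in LOC124903696, 173 bp from CETP as the nearest coding gene (chromosome 16: 56984019–56986264, 12.4 and 12.8). POM121C encodes a nuclear pore protein, MRPL48 a mitochondrial ribosomal protein and CETP a plasma protein that transfers cholesteryl esters between lipoproteins. Lost and gained H3K27ac regions had median widths of 489 and 477 bp, against 1804 bp for the 33728 kept regions, and 9.06% and 12.7% of them touched a gene end window, against 38.6% of kept ones. Read pileups were scaled in both NC1235 H3K27ac lists and in no other list, so these regions coincide with a difference in pileup scaling.

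H2AZ had 2780 lost and 1615 gained regions among 63461, and the replicate number gave 2326 and 286. Its lost regions of highest fold enrichment lay in LOC105372633, 3930 bp from ELMO2 as the nearest coding gene (chromosome 20: 46410546–46411117, 14.5 and 12.5), in EFHC2 (chromosome X: 44222840–44223911, 11.5 and 14.9) and 280 bp from LOC105372899 (chromosome 1: 209565961–209566667, 11.5 and 11.2). Its gained regions lay 12547 bp from MTAP (chromosome 9: 21789599–21790088, 14.6 and 15.9), in KCNH2 (chromosome 7: 150977912–150978673, 13.2 and 11.9) and 3372 bp from LOC124904902, 15019 bp from PPP1R16B as the nearest coding gene (chromosome 20: 38790209–38790677, 14.1 and 11.3). KCNH2 encodes a potassium channel and MTAP an enzyme of methionine salvage. H3K36me3 had 2278 lost and 3648 gained regions among 81471, and the replicate number gave 3118 and 726. Lost H3K36me3 regions of highest fold enrichment lay in ALPK1 (chromosome 4: 112438336–112440040), WNK1 (chromosome 12: 866201–867533) and MAP4K4 (chromosome 2: 101871383–101872169), all kinase genes. Gained ones lay at KLHDC7B (chromosome 22: 50548418–50550934), RAP1GAP2 (chromosome 17: 3011780–3012400) and HERC5 (chromosome 4: 88474940–88476931), an interferon-induced ligase of ISG15. In the weaker of their 2 libraries the median −log10 q of lost and gained regions was 4.64 and 5.07 for H2AZ and 3.87 and 3.99 for H3K36me3. Values of at least 10 were reached by 101 and 84 H2AZ regions and by 7 and 13 H3K36me3 regions. With an equal number of top peaks per library, H2AZ gave 2042 lost and 2025 gained regions and H3K36me3 gave 2913 and 2264. Within replicates 1 and 2, regions in NC1235 alone and in Si1235 alone numbered 10663 and 8253, then 10282 and 6551, for H2AZ. They numbered 5326 and 5835, then 7547 and 4596, for H3K27ac, and 14429 and 16305, then 10324 and 17276, for H3K36me3. With fewer libraries required, lost and gained counts became 9016 and 2271 for H2AZ, 4283 and 2959 for H3K27ac and 11333 and 4748 for H3K36me3 without NC1235 replicate 2, and 3700 and 6689, 3849 and 4463, and 3624 and 14069 without Si1235 replicate 2.

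**Figure D2:**
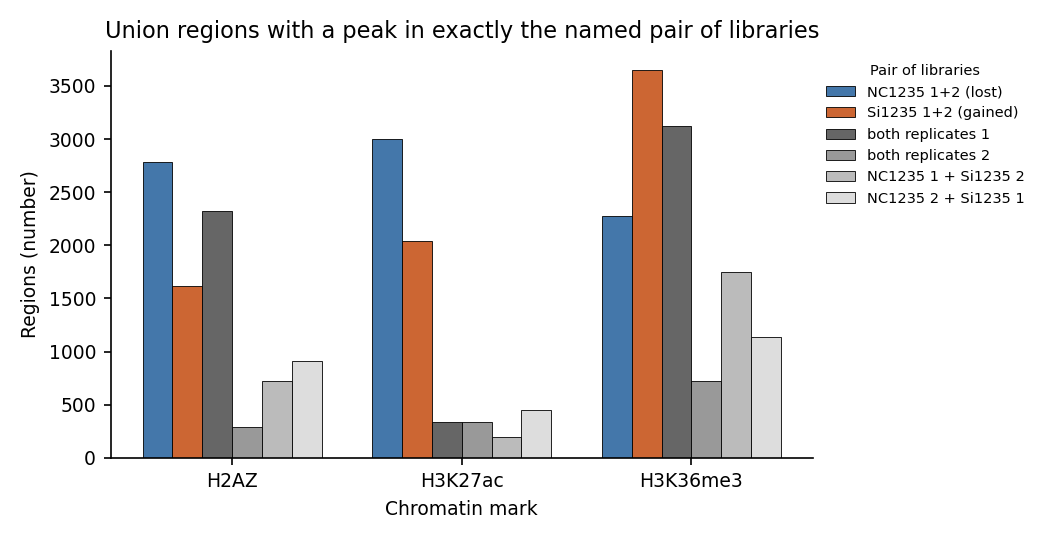
Number of union regions (y axis) with a peak in exactly the named pair of libraries, for each mark (x axis), with pairs of the same arm in color and the other pairs in grey. For H3K27ac the same-arm pairs hold 3003 and 2040 regions and no other pair more than 453.

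H3K27ac at gene ends differed at 81 genes of 16026 tested, with 37 higher and 44 lower in Si1235 (limma, adjusted p under 0.05). The calls include small differences, such as −1.575 points at LOC124905115, −3.525 at EIF2B4, 1.65 at FAM47E and 2.7 at PCNA-AS1. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell by 72.5 points, from 72.5 ± 4.24% of its window in NC1235 to 0 in both Si1235 libraries (n = 2 per arm, adjusted p = 0.0398). That window (chromosome 6: 36675463–36677462) is the upstream edge of a domain that stayed: peaks from 36678224 to 36681292 and from 36678702 to 36681320 were present in Si1235 replicates 1 and 2. PRKCH, a protein kinase C gene, fell by 69.6 points (limma adjusted p = 0.0236). The H3K27ac domain at that window stayed, starting at 61550919 and 61550734 in NC1235 and at 61551949 and 61552047 in Si1235. ARSI, a sulfatase gene, rose from 20.2 ± 1.20% to 77.6 ± 1.94% (limma adjusted p = 0.0270). CETP rose from 0 in both NC1235 libraries to 40.6 ± 1.13% (limma adjusted p = 0.0398). Strand was not given, so the windows of ARSI, CETP and PRKCH may lie at the gene end away from the promoter. The same holds for other genes outside the checked ones. The other named genes that rose were SPNS2-AS1 by 48.5 points, LINC02889 by 46.0, TSNAXIP1 by 37.3, PACSIN3 by 30.2, LOC105371934 by 26.4 and LOC124904065 by 25.1. The others that fell were TP73-AS2, with −66.1 points, LOC105379015 with −66.0, LOC105374515 with −50.9, LOC124900595 with −44.8, LINC00640 with −44.6 and LOC105378231 with −43.8. LINC00640 and LOC124900595 share 1 region. Counted as separate regions, the 81 genes lie in 72, with 34 higher and 38 lower, and the 17 named ones in 16. Cover at EZH2, the H3K27 methyltransferase gene, went from 100% in both NC1235 libraries to 83.0 ± 0.460% (limma adjusted p = 0.0202). EZH2 was chosen after its values were seen. The difference is a break between called peaks in Si1235, at 148884117–148884464 in replicate 1 and 148884127–148884461 in replicate 2. Peaks lay on both sides of the break, so no loss of the mark there can be read from it.

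At 73 of the 81 genes, in 65 separate regions, the region that held most of the difference had a peak in all 4 libraries. These calls therefore record the extent of peaks within the window, not presence or absence of the region. Some were shifted edges, as at CDKN1A and PRKCH, or breaks between peaks, as at EZH2 and PACSIN3. At LOC105379015 a narrower peak remained, at 68949520–68951537 in NC1235 replicate 1 and 68949676–68950081 in Si1235 replicate 1. Its fold enrichment was 15.2 and 15.3 in the NC1235 libraries and 3.99 and 3.80 in the Si1235 libraries. At 6 genes neither library of the arm with less cover had a peak in that region, among them CETP, LINC02889, LOC124904065 and SPNS2-AS1, which rose, and TP73-AS2, which fell. Read pileups were scaled in both NC1235 H3K27ac lists and in neither Si1235 list, so the 81 calls coincide with a difference in scaling between the arms. Why those pileups were scaled is not given in the sources used here. The arms did not overlap and differed by at least 20 points at 432 genes higher and 378 lower, against 14 and 146 for the split by replicate number and 70 and 21 for the crossed split. Arms did not overlap at 41.1% of tested genes, against 23.7% for the replicate number and 19.1% for the crossed split, and chance gives 27.96% with the ties counted. The split by replicate number called 1 gene higher and 15 lower, and the crossed split called 0, with 451 at unadjusted p under 0.05 in limma against 2255 for the arms. The counts of higher and lower calls became 315 and 10 without NC1235 replicate 1, 237 and 4 without NC1235 replicate 2, 7 and 266 without Si1235 replicate 1, and 3 and 129 without Si1235 replicate 2. Of the 17 named calls, EZH2 included, 4, 3, 2 and 1 stayed past the threshold in that order. With windows of ± 2.5 kb limma called 3 higher and 6 lower, and 2 of the 17 stayed past the threshold, against 6 with quantile normalization.

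**Figure D3:**
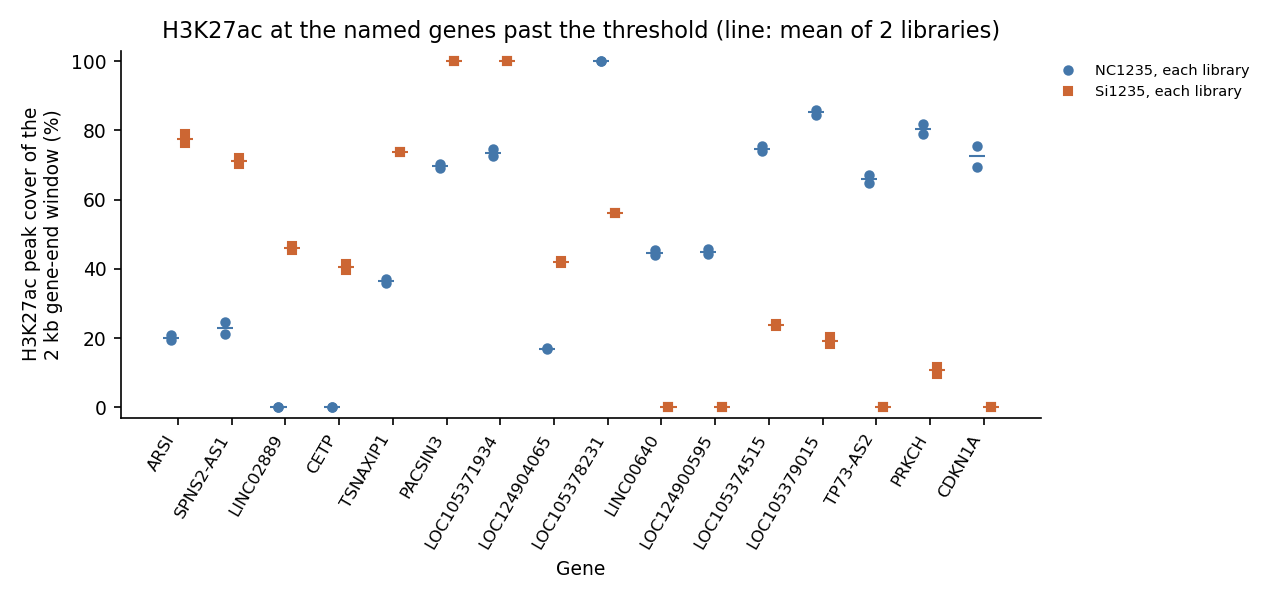
H3K27ac peak cover of the 2 kb gene end window (y axis, percent) at the genes past the threshold that the naming rule gives (x axis), with each NC1235 library as a blue circle, each Si1235 library as an orange square and lines at the means of 2 libraries. At CDKN1A both NC1235 libraries lie at 69.5 and 75.5% and both Si1235 libraries at 0.

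Among the gene lists, interferon and nucleic acid response genes rose in H3K27ac, with 18 of 25 tested members higher, 7 equal and 0 lower (camera adjusted p = 0.0176; adjusted p = 0.936 with an estimated correlation). No member passed over all genes tested with limma. CXCL11, a chemokine gene, was the 1 that passed adjusted over the list alone, and had 24.4 and 23.1% in Si1235 and 0 in both NC1235 libraries, and OASL differed by 18.7 points. Basal and myoepithelial markers fell, with 6 of 10 tested members lower, 4 equal and 0 higher (camera adjusted p = 0.0289; adjusted p = 0.936 with an estimated correlation). None of these passed over all genes with limma, and the integrin genes ITGA6 and ITGB4 were the 2 that passed adjusted over the list alone, with −20.8 and −8.45 points. The difference at TRIM29 was −35.2 points and passed neither. Leaving out Si1235 replicate 1 or 2 took the interferon list to adjusted p = 0.0759 and 0.0870 and the basal list to 0.242 and 0.0870, and NC1235 replicate 2 took the basal list to 0.391. Both lists also coincide with the scaled pileups of the NC1235 H3K27ac lists.

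The other 17 lists tested for H3K27ac did not pass, with camera adjusted p from 0.220 to 0.925, and replication licensing genes were at 0.862. Of the 30 cell cycle genes, 1 passed over all genes and 1 adjusted over the list alone, which was CDKN1A. Of the 19 MYC and stem factor genes, 1 passed over all genes, EZH2, and 4 adjusted over the list alone, EZH2, CD24, KLF4 and SOX9. ROBO4 of the endothelial list, CD3E of the immune list and SNAI1 of the mesenchymal list passed adjusted over their list alone. The members with the largest differences in these lists and in the endothelial list, too small for camera, none past the threshold over all genes, were MCM6 with 9.98 points and MCMBP with −9.98 among licensing genes, MCM10 with −12.6 and DBF4B with −11.2 among origin firing genes, and POLD1 with 19.5 and FEN1 with 12.8 among replication fork genes. For chromatin machinery they were HDAC1 with 13.9, HDAC5 with −12.6, EPC1 with −13.9, ZNHIT1 with 13.6, KDM4B with −14.6 and NSD1 with 14.1. For HER2 and its signalling they were TCAP with 28.4, PNMT with 21.5, IRS1 with −19.2 and BRAF with −12.7. For the cell cycle, p53, apoptosis and growth they were CDC25B with 25.9, SESN2 with 17.7, BBC3 with 9.63, BID with 18.7, CASP9 with −7.10, RPS28 with 12.5, RPS15 with −9.90, H3C12 with 15.7 and H2BC14 with 15.1. For cell identity they were CD24 with 17.6, SOX2 with 17.2, CLDN3 with 12.1, EPCAM with −9.10, SNAI1 with −15.5, SPARC with −12.2, CD3E with 31.2, CD8A with −12.1, ROBO4 with 60.9 and CDH5 with 6.90. For the mesenchymal list the median was above 0 while its mean, −1.03 points, and its test pointed down.

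H2AZ cover of gene ends showed the largest differences that separated the arms, none of them past the threshold, at genes of several kinds. Cover at IFI44, an interferon-induced gene, was 82.2 and 78.4% in NC1235 and 14.5 and 18.8% in Si1235, and at SAMD9, an interferon-responsive antiviral gene, it was 78.0 and 76.0% against 16.2 and 17.7%. The differences were −76.7 points at SMILR, −67.9 at CLCA2 and −63.2 at LOC101928933. They were 65.3 at LOC124907747, 60.6 at UBTF, an RNA polymerase I factor, 59.8 at LINC02595, 55.5 at ADGRF1 and 55.2 at KITLG, the ligand of the receptor KIT. Limma called 0 of 17364 genes for H2AZ, with 702 higher and 358 lower at unadjusted p under 0.05, against 1969 in all for the split by replicate number and 276 for the crossed split. Arms did not overlap at 31.9% of genes, against 44.6% for the replicate number and 18.5% for the crossed split, where chance gives 31.7% with the ties counted. A non-overlapping difference of at least 20 points was seen at 352 genes higher and 221 lower, against 7 and 881 for the replicate number.

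Genes of the HER2 amplicon, which adjoin on chromosome 17, rose in H2AZ, with 12 of 13 tested members higher and 0 past the threshold either over all genes or adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.963 with an estimated correlation). GSDMB differed by 16.4 points and PNMT by 12.6, and the median of the list was 3.43 points, against 1.16 for all tested genes. The interferon and nucleic acid response list fell (camera adjusted p = 0.0236; adjusted p = 0.963 with an estimated correlation), while 13 of its 24 tested members were higher and 11 lower. Its mean was −8.04 points and its median 0.163, which quantile normalization took to −1.30. No interferon member passed over all genes with limma, and IFI44 and IFI44L were the 2 that passed adjusted over the list alone, with −63.7 and −29.1 points. The difference at OAS3 was −47.6 points and passed neither. With the replicate number as a block, camera put the amplicon list at adjusted p = 0.0510 and the interferon list at 0.0504. Without NC1235 replicate 1 and Si1235 replicate 2 in turn the amplicon list was at 0.175 and 0.366. Without NC1235 replicate 1, Si1235 replicate 1 and Si1235 replicate 2 in turn the interferon list was at 0.185, 0.173 and 0.138, and with an equal number of top peaks it was at 0.0948.

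The other 16 lists tested for H2AZ did not pass, with camera adjusted p from 0.0643 for replication-dependent histone genes to 0.894, and licensing genes were at 0.498. The largest differences of these lists, and of the immune and endothelial lists that were too small for camera, were −10.2 points at MCM5 and −10.2 at ORC3, an origin recognition complex gene, 9.85 at GINS2, 7.78 at RECQL4, −41.6 at POLE, a DNA polymerase gene, and −16.4 at RFC3, none past the threshold. For histones and chromatin machinery they were −33.2 at H2BC14, −29.1 at H2BC13, 22.4 at BRD2, 21.6 at KAT5, 11.8 at ZNHIT1, 9.85 at ACTR6, 24.3 at PHF1 and 12.6 at KDM8. For signalling and growth they were 20.4 at HRAS, 17.8 at SHC1, 16.6 at CDKN1B, −13.3 at CDK2, 14.9 at ATR, 12.5 at BBC3, 20.1 at BCL2L11, 15.3 at BAD and −22.8 at RPL18. For cell identity they were 26.9 at CDH1, 14.6 at MUC1, 30.8 at ITGB4, 20.9 at KRT5, 19.4 at S100A4, 15.8 at FAP, 24.5 at ALDH1A3, 16.7 at MYCN, −13.3 at CD3E, 3.65 at CD8A, 14.6 at ROBO4 and 11.3 at FLT1. Leaving out a single library moved some of these widely, among them BRD2 between 0.275 and 44.4 points, HRAS between 0.9 and 39.95 and CDKN1B between 1.55 and 31.55. Others held, such as KAT5 between 19.9 and 23.2. FAP of the mesenchymal list and SESN1 of the p53 list passed adjusted over the list alone. The median or mean and the test differed in sign for 6 H2AZ lists, which were the interferon, H2AZ machinery, MYC and stem factor, origin firing, replication fork and ribosomal protein lists.

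H3K36me3 over gene bodies was higher in Si1235 across interferon and nucleic acid response genes, with 20 of 21 tested members higher. The list rose (camera adjusted p = 3.41e-11; adjusted p = 0.988 with an estimated correlation), with a median of 13.4 points, and it passed without each library in turn. OAS2, which senses double-stranded RNA, had 27.96 ± 6.68% in NC1235 and 72.0 ± 2.63% in Si1235 (SD, n = 2), and IFIT1 had 14.9 ± 3.68% and 53.5 ± 6.78%. IFI44L differed by 35.4 points, and OASL had 28.2 and 17.7% in Si1235 and 0 in both NC1235 libraries. The arms did not overlap at 15 of the 21 members, 11 passed adjusted over the list alone, and 0 passed over all genes tested. HERC5, outside the list, had 12.2 ± 1.20% in NC1235 and 62.3 ± 3.20% in Si1235.

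**Figure D4:**
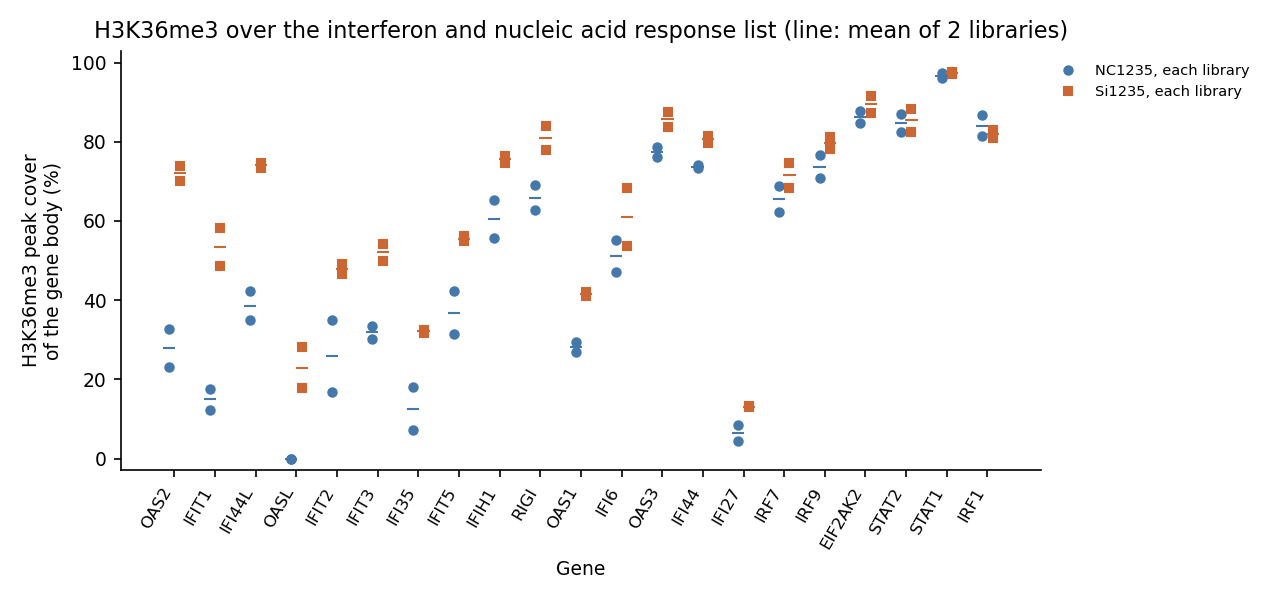
H3K36me3 peak cover of the gene body (y axis, percent) at the 21 tested members of the interferon and nucleic acid response list (x axis), with each NC1235 library as a blue circle, each Si1235 library as an orange square and lines at the means of 2 libraries. The mean is higher in Si1235 at 20 members and lower at IRF1.

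Mesenchymal genes fell in H3K36me3, with 6 of 6 tested members lower (camera adjusted p = 0.00261; adjusted p = 0.988 with an estimated correlation), among them SPARC with −13.7 points and SNAI1, a transcriptional repressor gene, with −11.8. Cell cycle genes fell as a list, with 17 of 26 tested members lower (camera adjusted p = 0.0113; adjusted p = 0.988 with an estimated correlation). The cyclin-dependent kinase genes CDK1 and CDK2 had 77.6 ± 3.73% and 31.1 ± 5.85% in NC1235 and 56.7 ± 9.04% and 10.2 ± 9.08% in Si1235 (SD, n = 2). No member of either list passed over all genes or adjusted over the list alone. Without NC1235 replicate 2 or Si1235 replicate 1 the cell cycle list was at adjusted p = 0.172 and 0.0531. Outside the lists the largest non-overlapping differences, none past the threshold, were 56.3 points at CTH, an enzyme of cysteine synthesis, 50.8 at DNAJB7, 50.8 at COTL1, 50.2 at HERC5 and 47.4 at RFNG. They were −49.7 at EDN2, an endothelin gene, −47.2 at ITGB1BP2, −43.2 at CASP14, −34.5 at TMEM106C and −32.2 at TM4SF1. Leaving out a single library moved ITGB1BP2 between −70.5 and −23.9 points. Limma called 0 of 8349 genes, with 460 higher and 203 lower at unadjusted p under 0.05, against 1136 in all for the split by replicate number and 23 for the crossed split. With quantile normalization limma called 65 higher and 28 lower, and the median change of all genes went from 0.694 to −0.515 points. Without NC1235 replicate 1, NC1235 replicate 2, Si1235 replicate 1 and Si1235 replicate 2 in turn it called 104 and 10, 14 and 23, 36 and 22, and 106 and 4. Arms did not overlap at 34.0% of genes, against 55.8% for the replicate number and 9.94% for the crossed split, where chance gives 33.3%. A non-overlapping difference of at least 20 points was seen at 147 genes higher and 42 lower, against 0 and 110 for the replicate number.

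The other 14 lists tested for H3K36me3 did not pass, with camera adjusted p from 0.163 to 0.949, and licensing genes were at 0.180, with 5 higher and 11 lower of 16. The largest differences of these lists, and of the histone and endothelial lists that were too small for camera, were −18.0 points at GMNN, the licensing inhibitor geminin, −9.92 at MCM6, 19.7 at RECQL4, 16.97 at DBF4B, 14.2 at FEN1 and −9.05 at POLD3, none past the threshold. For histones and chromatin machinery they were −16.7 at H2BC12, 7.55 at H3C6, 17.8 at KAT2A, 15.0 at HDAC10, −11.4 at ACTR6, 10.7 at RUVBL2, −13.8 at PSIP1 and −4.66 at KDM2A. For signalling and growth they were 18.1 at GSDMB, 16.9 at STARD3, 18.8 at AKT1, 10.1 at IRS2, −18.1 at RRM2B, −17.9 at BTG2, 20.5 at BCL2L1, 8.42 at BAD, 9.33 at RPS15 and 8.40 at RPS13. For cell identity they were 42.8 at KLF4, 16.5 at NOTCH1, 7.82 at ELF3, 7.20 at CLDN7, −20.3 at TRIM29, −4.72 at KRT5 and −0.414 at PECAM1. KLF4 and H2BC12 passed adjusted over the list alone. The median or mean and the test differed in sign for 2 lists, HER2 signalling and MYC and stem factors.

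Changes were then compared between marks across genes, which are not independent replicates. Across 7688 genes the change in H3K27ac and that in H3K36me3 had a Pearson correlation of 0.172 and a Spearman correlation of 0.142, against 0.0577 and 0.0497 for the split by replicate number. H2AZ and H3K27ac gave 0.127 and 0.131 across 14924 genes, against 0.0512 and 0.0570. H2AZ and H3K36me3 gave −0.0142 and 0.0205 across 7645 genes, against 0.0611 and 0.0599. Of 3003 lost H3K27ac regions 174 lay on lost and 16 on gained H2AZ regions, of 2040 gained ones 17 and 59, and of 33728 kept ones 933 and 653. The control used in peak calling is not given, so the marks of an arm may share that arm's 1 input.

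H3K9ac had 1 library per arm, so its differences have no replicate check and no test. The libraries shared most peaks, with 77.8% of NC1235 peaks (95% interval 77.4 to 78.1) and 77.8% of Si1235 peaks (77.4 to 78.1) overlapping the other arm. The 8 largest increases were 80.6 points at LOC124902184, 73.7 at LOC101929494, 70.9 at LINC01629, 67.9 at LINC02884, 64.7 at LINC02044, 64.5 at NTRAS, 63.2 at LOC124901274 and 58.3 at C17orf99. The 8 largest decreases were −80.8 at ATP6V1B1, a proton pump subunit gene, −79.9 at SP6, −78.5 at LOC102724720, −78.5 at TBL1XR1, a corepressor subunit gene, −72.2 at SH3RF3-AS1, −65.2 at LINC02092, −62.8 at COL23A1, a collagen gene, and −62.3 at LINC01767. Of 18395 genes, 591 were higher and 882 lower by at least 20 points, and ERBB2 was covered in full in both arms. The interferon list had a median of −0.475 points, at percentile 19.6 of 10000 random lists matched on mean cover. The highest percentile of any list was 92.8, for basal markers, and the lowest was that of endothelial markers, with a median of −8.50 points over 5 genes.

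ChIRP recovered DNA in the NC1235 arm with probes whose RNA is not given, and no control pull-down is given in the sources used here, so its peaks may include probe background. The strongest ChIRP peaks lay 8173 bp from LOC107985549, with XBP1 as the nearest coding gene at 30260 bp (chromosome 22: 28830830–28831833, fold enrichment 231), 125 bp from LOC105375977 (chromosome 9: 13487633–13488431, within the H3K27ac domain near LINC01235, 214), in LOC105373220 (chromosome 1: 238406860–238407571, 189), 20469 bp from TAB3 (chromosome X: 30788510–30806972, 187) and in LINC01235 itself (chromosome 9: 13406057–13408719, 169). XBP1 encodes a transcription factor of the unfolded protein response. LINC01235 held 3 ChIRP peaks over 13.5% of its length. Of the ChIRP peaks 6.75% touched a gene end, 54.8% lay elsewhere in genes and 38.5% lay outside them. The share of ChIRP peaks that overlapped NC1235 peaks was 3.33% for H2AZ, 4.23% for H3K27ac, 7.52% for H3K36me3 and 4.53% for H3K9ac, which was 1.38, 1.34, 1.23 and 1.38 times the mean of random placements. Placement within occupied 100 kb bins, chosen after seeing the data, gave 1.27, 1.23, 1.13 and 1.26 times. Each gave a one-sided permutation p of 0.001, the smallest that 1000 placements can give, and 1 ChIRP library gives no replicate check. Lost and gained regions held a ChIRP peak less often than kept ones, with odds ratios of 0.661 and 0.653 for H2AZ, 0.433 and 0.368 for H3K27ac and 0.167 and 0.227 for H3K36me3 (Fisher's exact test, largest adjusted p = 9.62e-06). Kept regions were wider. With regions matched on width in 5 bins, the pooled odds ratios were 1.04 and 1.09, 1.14 and 1.07, and 0.672 and 0.911. Of these, lost H3K36me3 regions alone passed, with an adjusted p of 0.00771 (Mantel-Haenszel test). Their median width was 672 bp against 3020 bp for kept ones. Widths can still differ within a bin, so width is not excluded there.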

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

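Windows at both gene ends, ChIRP placement in occupied bins, counts of non-overlapping changes and the sterol list were chosen after the results were seen; all other alternatives were fixed beforehand. With a library left out, the lone library of an arm is assumed to vary like the others. Of the values that answer a comparison, 163 stayed the same, 51 moved, 23 became weaker and 12 reversed; of the others 2190 stayed the same, 65 became stronger, 122 weaker and 58 reversed. With fewer libraries or genes the change follows from the construction; elsewhere the cause was not tested.

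With an equal number of top peaks, the H3K36me3 log2 ratio of covered length was −0.0184, gained H3K36me3 regions were 2264 and the H2AZ interferon list was at adjusted p = 0.0948 (camera). With −log10 q of at least 5, gained H3K36me3 regions were 2169, NFIB and PECAM1 H3K36me3 changes were 0.103 and 2.26 points, and H3K9ac overlap was 81.4% of NC1235 and 80.5% of Si1235 peaks, against 69.8% and 69.6% where at least 50% of the peak had to overlap. Merging within 500 bp gave 1335 lost and 2301 gained H3K36me3 regions. In limma the arcsine scale called 66 higher and 75 lower genes for H3K27ac and 6 and 2 for H3K36me3, quantile normalization 26 and 28, and 65 and 28, and windows of ± 2.5 kb 3 and 6 for H3K27ac. KRT5 was at −3.53 points for H2AZ with ± 2.5 kb, and in the 3′ part of the gene body KRT5 and SNAI1 were at 4.43 and 1.37 for H3K36me3. With an estimated correlation, camera gave adjusted p = 0.963 for the HER2 amplicon and interferon lists of H2AZ, 0.936 for the interferon and basal lists of H3K27ac and 0.988 for the interferon, mesenchymal and cell cycle lists of H3K36me3. Matched on width in 5 bins, ChIRP odds ratios were 1.04 and 1.09 for H2AZ, 1.14 and 1.07 for H3K27ac and 0.911 for gained H3K36me3 regions.

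The replicate numbers are not established as pairs, and deviations from the arm means correlated at 0.177, 0.0622 and 0.296 for H2AZ, H3K27ac and H3K36me3. With the replicate number as a block limma called 0 genes higher and 0 lower for each mark, with 1413, 1909 and 1838 at unadjusted p under 0.05, and 0 of the 17 named H3K27ac calls stayed past the threshold. With the block camera gave adjusted p = 0.0510 for the HER2 amplicon and 0.0504 for the interferon list of H2AZ, and the direction reversed for H2AZ MYC and stem factors (0.966) and H3K27ac cell cycle (0.993).

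With each library left out in turn, log2 ratios of covered length ranged from −0.21 to 0.11 for H2AZ, −0.0860 to 0.00913 for H3K27ac and −0.13 to 0.17 for H3K36me3. Those of peak number ranged from −0.192 to −0.00419 for H2AZ, −0.0653 to 0.0448 for H3K27ac and 0.114 to 0.234 for H3K36me3. Lost and gained regions ranged from 3700 to 9016 and 2271 to 6689 for H2AZ, 3849 to 5664 and 2694 to 4463 for H3K27ac, and 3624 to 11333 and 4748 to 14069 for H3K36me3. Genes called higher and lower in limma ranged from 3 to 315 and 4 to 266 for H3K27ac and 14 to 106 and 4 to 23 for H3K36me3. Camera adjusted p for H2AZ ranged from 0.00277 to 0.366 for the HER2 amplicon, 0.0291 to 0.185 interferon, 0.514 to 0.989 cell cycle, 0.572 to 0.891 H2AZ machinery, 0.559 to 0.927 H3K36 machinery, 0.366 to 0.989 luminal, 0.650 to 0.989 MYC and stem, 0.634 to 0.989 origin firing, 0.447 to 0.954 replication fork and 0.572 to 0.908 ribosomal lists. For H3K27ac it ranged from 0.0290 to 0.391 for the basal, 0.000187 to 0.0870 interferon, 0.744 to 0.979 cell cycle, immune and replication fork, 0.886 to 0.987 H2AZ machinery, 0.833 to 0.979 luminal, 0.744 to 0.960 mesenchymal, 0.330 to 0.960 origin firing, 0.934 to 0.987 histone and 0.839 to 0.979 ribosomal lists. For H3K36me3 it ranged from 0.000596 to 0.172 for the cell cycle, 0.475 to 0.969 apoptosis, 0.897 to 0.994 HER2 signalling, 0.345 to 0.969 luminal, 0.733 to 0.994 MYC and stem, 0.805 to 0.994 p53 and 0.0356 to 0.969 ribosomal lists. Gene changes in points whose sign turned ranged for H2AZ from −27.4 to 0.9 at CD3E, −26.0 to 5.68 at MCM5, −5.73 to 21.3 at RECQL4 and −3.03 to 32.2 at ROBO4. For H3K27ac they ranged from −22.1 to 7.90 at CASP9, −27.9 to 3.63 at CD8A and −7.90 to 21.7 at CDH5. For H3K36me3 they ranged from −9.62 to 24.7 at H3C6, −11.7 to 2.25 at KRT5, −2.50 to 1.05 at NFIB, −4.44 to 3.62 at PECAM1 and −23.7 to 0.0762 at SNAI1.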

Other observations

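The list of sterol synthesis genes was chosen after 4 of its members, MVK, INSIG1, CYP51A1 and ACAT2, had been seen among the changes, so it is given with and without them. H3K36me3 over these genes fell, with 23 of 25 tested members lower (camera adjusted p = 5.96e-12; adjusted p = 0.458 with an estimated correlation), and it fell without the 4 as well (adjusted p = 9.69e-08; adjusted p = 0.458 with an estimated correlation). MVK, the mevalonate kinase gene, had 54.4 and 35.8% in NC1235 and 15.6 and 15.7% in Si1235, and HMGCS1, an early enzyme of the pathway, had 74.5 and 72.8% against 58.6 and 50.3%. No member passed over all genes in limma, and 8 lower and 1 higher passed adjusted over the list alone, or 2 lower and 1 higher without the 4. H2AZ at the gene ends of the same list rose, with 21 of 23 tested members higher (camera adjusted p = 0.00182, or 0.00131 without the 4; adjusted p = 0.458 with an estimated correlation for both). FDPS, the farnesyl diphosphate synthase gene, had 46.3 and 46.3% in NC1235 and 97.2 and 74.6% in Si1235. No member passed over all genes in limma, and 3 higher passed adjusted over the list alone. Without NC1235 replicate 2 the H2AZ result was lost, at adjusted p = 0.121, or 0.183 without the 4. H3K27ac over the list did not pass, at adjusted p = 0.0722, or 0.374 without the 4 genes, and became 0.0490 without Si1235 replicate 1.

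For the interferon and nucleic acid response genes, the tests of depth were chosen after the members' changes had been seen, and the test of binding before its value was seen. The median change of the list was at percentile 100 of random lists matched on mean cover for H3K27ac and at percentile 100 for H3K36me3, so depth or peak number acting alike on genes of similar cover does not account for it there. Random lists carry no correlation between members, and for H3K27ac the scaled pileups of both NC1235 lists stay open. For H2AZ it was at percentile 21.8, inside the range set for depth, but that reading was changed to open after the value was seen, since members went both ways, so depth and a real decrease cannot be told apart. The number of list genes with a ChIRP peak, 17 of 26, was at percentile 64.9 of random lists matched on length, so binding of LINC01235 there remains open. A response to the oligonucleotide itself was not tested, as the design has no untransfected group and no oligonucleotide arm beside NC1235 and Si1235.

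For the higher number of H3K36me3 peaks in Si1235, both tests were chosen after the result was seen. Union regions with a peak in both arms held 58.1% of the difference in mean peak number, those in Si1235 alone 144% and those in NC1235 alone −102%, so broad domains called as more and narrower pieces and added peaks elsewhere cannot be told apart. Merging peaks left 70.1% of the log2 difference at 500 bp, 57.4% at 1 kb and 14.03% at 10 kb, where separate peaks are joined as well. The lower background of the Si1235 libraries gave 27.9% of the difference at the slope between replicate numbers, so depth can be neither excluded nor taken as the cause. No biological explanation was tested.

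For the H3K27ac regions present in 1 arm alone, the test of depth was chosen after the result was seen and the test of local background before its value was seen. The gained regions were at least 3.49 times the highest count of the other pairings in every setting. Any property shared by the 2 libraries of an arm raises this ratio, and the scaled NC1235 lists do not give depth. The ratio therefore cannot decide whether depth plays a part. Read pileups were scaled in both NC1235 lists and in neither Si1235 list, so an effect of that scaling and a difference between the arms cannot be told apart. Local background was recovered at weak H2AZ peaks inside these regions, not from the H3K27ac lists. It was available in both arms for 449 of 3003 lost and 327 of 2040 gained regions. There its log2 ratio, Si1235 over NC1235, was 0.18 beyond kept regions in lost regions and −0.25 in gained ones. A local difference in background therefore remains open. No biological explanation was tested.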
